A study of Danio rerio with 15 samples.

How the data were processed

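The deposited intensity values are the output of Agilent Feature Extraction 10.7.1.1, per the file headers, and version 10.7 per the submitters' processing notes. Spot intensities were background-subtracted and spatially detrended on a linear scale before deposit, per the file headers, which also name the zebrafish build of the array's design. The arrays carried a single Cy3 label, per the labels' protocols, and RNA was extracted with Trizol. The series design states that hearts were pooled into 15 tubes and does not give the hearts per tube. The deposited value table holds log2 values made by the authors with a normalization that is not stated. Its columns had medians of 5.49 to 5.50 and a floor of 2.5 that held 14.8% to 15.2% of the values, and they correlated with the log2 processed signal of their own array at r = 0.992 to 0.999. Its scale was log2 and its centring stays unknown. It was used as an alternative.

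From the deposited intensities, log2 processed signals were taken and the 75th percentile of each array was subtracted. The 1417 control spots were left out, as were spots marked as outliers, 2 to 16 per array, among the other 43803 spots. The spots of 1 probe were averaged (50 probes lay on 5 spots each). Of 43603 probes, 33323 were well above background on at least 4 of the 15 arrays and were kept. Probes were named through their accession without version: 26094 matched 1 gene and 17509 did not, among them 25985 of 27351 with an NM accession that matched, and the others kept the name in the file. Where a gene had more than 1 probe (7723 genes), the probe of highest mean over all arrays stood for it, which left 21326 genes.

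Groups were compared in limma 3.58.1 (lmFit and eBayes, R 4.3.3, data.table at 1.17.8, statmod 1.5.0) with all 15 arrays in 1 fit, with 12 residual and 2.53 prior degrees of freedom, and Benjamini-Hochberg adjustment over all genes at 0.05. A standard error given with ± is the moderated one of that fit, and ± followed by SD is the spread between arrays. A gene not well above background on any array of a group has a bound only: the mean of the brighter group was set against the mean, over the dim group's arrays, of the higher of the gene's own signal and the lowest signal of any probe well above background. Such a bound is one on group means and takes no account of the spread between arrays. Gene lists (47, of which 13 hold cell type markers) were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, after 14 genes with a missing value were left out. Beside it stand camera with the correlation estimated, fry, and an exact two-sided permutation of the arrays' list scores. A list score is the median over the list's genes of the log2 value less the gene's mean over all arrays. Slide was read as a batch, and the consensus correlation of arrays on a slide was 0.0177. The normexp alternative added an offset of 50 to the signals, where the arrays' median intensities were 35.3 to 59.8. Such an offset makes the log2 differences of dim genes smaller by construction. A smaller median under normexp can therefore come from this setting, and its share was not tested.

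The lists, the design, the alternatives and the rule for named genes were fixed before the data were examined. The rule named, per comparison, the 10 largest changes in each direction among genes past the threshold with a symbol, filled to 5 with the genes of smallest p where fewer passed. It added the 3 members of smallest p of the mTOR, vacuolar ATPase, lysosomal and autophagy lists, the 4 members of smallest p in the list's direction for each other list past the threshold, and mtor, rptor, rps6kb1b, tfeb, lamp2, cyp1a, nppa and nppb. No tested probe carried the names rptor, tfeb and nppb.

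The limma fit and camera at its preset correlation were also run on 21326 simulated genes for the comparison of 1.8 ug/g with control. Gene means and spreads came from the real arrays, and 200 genes were changed at once in each of 5 runs. The other steps were not part of these runs. The fit recovered 39.6%, 80.8%, 90.4% and 96.8% of the genes changed 2, 4, 8 and 16-fold, with 161 calls per run of which 7.2 were false. A list of 40 genes shifted by 0.3 was called in 5 of 5 runs, and 0 of 50 unchanged lists were. The simulated genes were drawn independently of each other, so these runs cannot show how often lists of correlated genes are called falsely. On the real arrays, other splits called a median of 13, 13 and 11 lists at 0.15 and 1.8 ug/g against control and between the doses.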

Results

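Dieldrin, a chlorinated cyclodiene insecticide that blocks GABA-gated chloride channels, was given in the diet to adult female zebrafish, and gene expression was measured in their hearts. Fish 6 months of age were sampled at day 21 of feeding. Hearts were pooled, and the RNA of each pool was hybridised to its own one-colour Agilent array: 5 control pools, 6 pools fed 0.15 ug/g and 4 pools fed 1.8 ug/g. The number of hearts in a pool is not given, so a replicate here is a pool and not a fish. The 15 arrays lay on 4 slides, each of which held all 3 groups. The 75th percentile of spot intensity ran from 184 to 334 across the arrays, between 63.8% and 75.7% of spots were well above background, and 0 spots were saturated. Of the genes on the array, 21326 were bright enough to be tested, 11418 of them with a symbol. Across genes, which are not independent replicates, arrays of the same group correlated at r = 0.930 to 0.969 (31 pairs) and arrays of different groups at r = 0.936 to 0.969 (74 pairs). Levels are log2 signals relative to the array's 75th percentile, differences are log2 differences with their standard error from limma, and the number of arrays limits their precision.

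The comparison of the 0.15 ug/g diet with the control diet asks what the lower dose did to expression in the heart (6 treated and 5 control pools). Markers of red blood cells, liver, exocrine pancreas and arterial smooth muscle were higher as groups in the treated pools, and heat shock, GABA system and oocyte genes were lower as groups, while no single gene passed the test. None of these group differences held with an estimated correlation (adjusted p 0.321 to 0.840), and the oocyte difference rested on control replicate 3 (median -1.42, and -0.16 without it). Among the higher genes with a symbol, the smallest p belonged to acp5b, a tartrate-resistant acid phosphatase of lysosomes and osteoclasts, at +1.56 ± 0.30 (level -3.37 ± 0.47 SD in controls and -1.81 ± 0.52 SD in treated pools). The apolipoprotein B gene apobb.1 stood at +1.44 ± 0.34, mannose phosphate isomerase mpi at +1.33 ± 0.35, the transferrin receptor gene tfr1a at +0.94 ± 0.24 and the glucokinase gene adpgk at +0.58 ± 0.15. Among the lower genes, the growth hormone-releasing hormone gene ghrh stood at -0.88 ± 0.18, aimp1a, a scaffold protein of the tRNA synthetase complex, at -0.70 ± 0.15 and the homeobox gene otx2b at -0.54 ± 0.13. The deacetylase gene sirt2 stood at -0.54 ± 0.11, with 1 of its 2 probes in that direction. The hedgehog ligand gene ihha was not well above background on any treated array and was at least 1.94-fold lower there. In limma, 0 of 21326 genes passed an adjusted p under 0.05, and the smallest adjusted p was 0.916. At an unadjusted p under 0.05 there were 1134 genes, 425 higher and 709 lower, where chance alone gives 1066.

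Erythrocyte markers stood higher in the pools fed 0.15 ug/g, with 24 of 28 members above control and a median of +0.86. The red cell transcription factor genes gata1a and klf1 stood at +1.39 ± 0.41 and +1.28 ± 0.46, and cahz, the carbonic anhydrase of red cells, at +1.81 ± 0.65. Of 30 hepatocyte markers, 28 were higher, with a median of +0.82, among them the apolipoprotein genes apoa4b.1 (+1.95 ± 0.60) and apoa1a (+0.94 ± 0.40) and the retinol-binding protein gene rbp4 (+0.56 ± 0.29). Of 21 pancreatic acinar markers, 18 were higher, with a median of +0.97, among them the carboxypeptidase gene cpa5 (+1.67 ± 0.53) and the elastase genes ela2 (+1.24 ± 0.47) and ela2l (+1.61 ± 0.73). The elastase gene cela1.1, not well above background on any control array, had a bound of 1.26-fold higher. It was well above background on only 2 of the 6 treated arrays, so that bound rests largely on background. Of 10 smooth muscle and bulbus arteriosus markers, 8 were higher, with a median of +0.77, among them the elastic fibre genes fbln5 (+1.62 ± 0.67) and elnb (+2.32 ± 1.52), the actin gene acta2 (+1.55 ± 0.88) and the myosin gene myh11a (+0.82 ± 0.65). In limma's camera with its preset correlation, the adjusted p was 4.2e-14 for the erythrocyte, 2.9e-09 for the hepatocyte, 5.7e-06 for the acinar and 0.00563 for the smooth muscle markers. The adjusted p was 0.370, 0.547, 0.840 and 0.840 with an estimated correlation, so none of the 4 calls held. The exact permutation p of the erythrocyte score was 0.0303 (adjusted 0.712). Over all genes 0 members passed, and 1, 1, 0 and 0 passed when adjusted over the list alone. The medians with slide as a block were +0.95, +0.69, +1.06 and +0.96. Within slides the mean score was higher on 4, 3, 4 and 4 of the 4 slides. Without control replicate 11 the erythrocyte median was +0.56, without 0.15 ug/g replicate 10 or 7 the hepatocyte median was +0.49 or +0.52, and without control replicate 3 the smooth muscle median was +0.47. With the acinar, oocyte and hepatocyte scores as covariates the smooth muscle call ended (+0.03, adjusted p 0.764), and under normexp background correction the hepatocyte and acinar medians were +0.48 and +0.51.

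Heat shock genes stood lower in the pools fed 0.15 ug/g, with 27 of 29 members below control and a median of -0.31. The inducible chaperone genes hsp70l and hspa1b stood at -1.41 ± 0.51 and -1.08 ± 0.42, and the co-chaperone genes dnajb1a and ahsa1a at -0.73 ± 0.18 and -2.01 ± 0.74. Of 8 genes of GABA receptors and GABA synthesis, the system dieldrin acts on, 7 were lower, with a median of -0.32. The receptor subunit genes gabrb2a and gabrr3a stood at -0.78 ± 0.24 and -0.79 ± 0.46, the transporter gene slc6a1a at -0.33 ± 0.18, and gad1b, which makes GABA, at -0.54 ± 0.20 with 1 of its 2 probes in that direction. For these lists camera's adjusted p was 2.2e-05 and 0.00682. With an estimated correlation the adjusted p was 0.840 and 0.321, so neither call held. The GABA scores of the 6 treated pools, -0.287 to -0.165, lay below those of all 5 controls, -0.157 to 0.496, and the exact two-sided permutation p was 0.00216 (adjusted 0.102), the smallest these arrays can give. The fall of the GABA list was not larger at the higher dose. Its mean score was 0.17 in controls, -0.21 at 0.15 ug/g and -0.02 at 1.8 ug/g (-0.17 to 0.13). Within slides the GABA score at 1.8 ug/g was lower than control on 3 of the 4 slides (shifts -0.47 to +0.25). The GABA list passed camera in neither comparison with 1.8 ug/g. For the heat shock scores the exact permutation p was 0.195. Adjusted over the list alone, 1 heat shock and 1 GABA gene passed, and 0 over all genes. Slide as a block gave medians of -0.32 and -0.25. Within slides the mean score was lower on 3 and 4 of the 4 slides. The heat shock median was -0.50 without control replicate 3 and -0.15 without control replicate 11, and the GABA median was -0.19 without control replicate 4. The GABA call also ended with no filter on dim probes (median -0.27, adjusted p 0.131), under normexp background correction (-0.09, 0.0822) and with the acinar, oocyte and hepatocyte scores as covariates (-0.24, 0.161), where the heat shock median was -0.57.

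Oxidative stress, inflammation and leukocyte genes stood higher by smaller amounts in the pools fed 0.15 ug/g. Oxidative stress genes had 22 of 35 members higher and a median of +0.04, with gpx1a, a glutathione peroxidase, at +0.86 ± 0.27, the thioredoxin inhibitor gene txnipa at +0.56 ± 0.16, the ferritin gene fth1a at +0.39 ± 0.18 and the superoxide dismutase gene sod1 at +0.23 ± 0.12. Inflammation and cytokine genes had 32 of 44 higher and a median of +0.15, with the acute phase gene saa at +1.44 ± 0.47, the NF-kB inhibitor gene nfkbiab at +0.84 ± 0.42, the gelatinase gene mmp9 at +0.88 ± 0.54 and the interferon regulator gene irf7 at +0.43 ± 0.27. Leukocyte markers had 30 of 41 higher and a median of +0.22, with the neutrophil genes mpx and lyz at +1.61 ± 0.75 and +1.38 ± 0.77, the T cell kinase gene zap70 at +0.85 ± 0.55 and laptm5 at +0.67 ± 0.42. Their camera adjusted p was 0.00563, 0.0108 and 0.00814. With an estimated correlation the adjusted p was 0.370, 0.840 and 0.844, and 0 members passed over all genes or adjusted over the list alone. Blocked by slide, the medians were +0.04, +0.20 and +0.23. Within slides the mean scores were higher on 3, 3 and 2 of the 4 slides. Single arrays decided these calls. Without control replicate 3, 4 or 11 or 0.15 ug/g replicate 10 the inflammation call ended (medians +0.02, +0.20, +0.09 and +0.12). Without control replicate 4 or 11 or 0.15 ug/g replicate 10 the leukocyte call ended (medians +0.26, -0.11 and +0.03). Without control replicate 1 the medians were +0.38 and +0.50 and without 0.15 ug/g replicate 9 the inflammation median was +0.26. The oxidative stress call ended without control replicate 4 (+0.03), and its median was +0.08, +0.08, +0.06 and +0.09 without control replicates 14, 3, 1 and 11 and +0.05, +0.13 and +0.06 without 0.15 ug/g replicates 15, 9 and 7. With the acinar, oocyte and hepatocyte scores as covariates the 3 calls ended (oxidative stress +0.07, inflammation -0.01 and leukocyte +0.11), the oxidative stress and leukocyte calls ended under normexp background correction (+0.08 and +0.15), and the inflammation and leukocyte calls ended with array weights (+0.10 and +0.05).

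Ovary and oocyte markers separated 1 control pool from the rest. At 0.15 ug/g 17 of 18 members were below control, with a median of -1.42, and at 1.8 ug/g 17 of 18 were below control, with a median of -0.69. The oocyte-secreted factor gene bmp15 stood at -0.91 ± 0.29 and -0.77 ± 0.32 at the 2 doses, the oocyte linker histone gene h1m at -2.01 ± 0.89 at 0.15 ug/g, and the egg envelope genes zp3a.2 and zp3d.2 at -1.13 ± 0.77 and -0.66 ± 0.46 at 1.8 ug/g. The mean score of the list was 5.26 on control replicate 3 and between -0.85 and 0.71 on the other arrays. The adjusted p of camera was 0.000742 and 0.0322, and with an estimated correlation the adjusted p was 0.840 and 0.974. With slide as a block the medians were -1.77 and -0.82, and the score was lower on 3 of the 4 slides at each dose. Without control replicate 3 both calls ended and the medians were -0.16 and +0.21, and both ended with probes well above background on every array (-0.41 and -0.73). Under normexp background correction the first median was -0.75. Without control replicate 3 and 1.8 ug/g replicate 8 together, the list passed at 1.8 ug/g in the other direction (+0.50, adjusted p 0.0107). The call at 1.8 ug/g also ended without 1.8 ug/g replicate 5 or 8 (medians -0.40 and -0.43), and no member passed over all genes or adjusted over the list alone.

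The comparison of the 1.8 ug/g diet with the control diet asks what the higher dose did (4 treated and 5 control pools). Genes of digestive enzymes made by the exocrine pancreas stood higher as a group in the pools fed 1.8 ug/g, and immediate early genes, which switch on within minutes of a stimulus, were higher too. Neither group difference held with an estimated correlation (adjusted p 0.155 for each). The elastase gene ela2 stood at +2.49 ± 0.52 (level 0.10 ± 0.60 SD in controls and 2.59 ± 0.91 SD in treated pools), ela2l at +3.55 ± 0.81 and ela3l at +3.69 ± 0.94, and the elastase gene cela1.1, not well above background on any control array, was at least 3.56-fold higher. The immediate early gene ier2a stood at +1.47 ± 0.33 (level 2.18 ± 0.73 SD in controls and 3.65 ± 0.58 SD in treated pools). The semaphorin gene sema3b, not well above background on any control array, had a bound of 1.36-fold higher. It was well above background on only 2 of the 4 treated arrays, so that bound rests partly on background. Among the lower genes, ihha was not well above background on any treated array and was at least 1.68-fold lower, and the phosphatase subunit gene ppp2r2bb, also dim in the treated pools, was at least 1.26-fold lower. The Ras-association gene rassf4a stood at -0.89 ± 0.21, the ion channel gene calhm2.1 at -1.32 ± 0.32 and the syntaxin-binding gene stxbp1a at -1.32 ± 0.32. Of these, rassf4a was well above background on only 1 of the 4 treated arrays, so its level there is mostly background. In limma, 0 of 21326 genes passed an adjusted p under 0.05, and the smallest adjusted p was 0.9996. At an unadjusted p under 0.05 there were 818 genes, 385 higher and 433 lower, where chance alone gives 1066. In data simulated for this comparison, 200 genes were changed at once, by 2 to 16-fold. There 39.6% of genes changed 2-fold and 80.8% of genes changed 4-fold were recovered. Recovery where only a few genes change was not simulated, so these shares do not apply to that case.

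All 21 pancreatic acinar markers were higher in the pools fed 1.8 ug/g, with a median of +2.57. The mean score of the list was -1.09 ± 0.83 SD in controls (n = 5), -0.12 ± 1.33 SD at 0.15 ug/g (n = 6) and 1.496 ± 1.23 SD at 1.8 ug/g (n = 4), and the 4 arrays of the 1.8 ug/g diet, at 0.73 to 3.33, lay above all 5 controls, at -1.86 to -0.07. Of 33 immediate early genes, 29 were higher, with a median of +0.57. The AP-1 gene fosab stood at +1.79 ± 0.53, btg2 at +1.63 ± 0.52 and jun at +0.78 ± 0.27. In camera the adjusted p was 2.0e-28 for the acinar markers and 2.2e-11 for the immediate early genes. The adjusted p was 0.155 for both with an estimated correlation. Neither call held. In an exact two-sided permutation of the array scores p was 0.00794 (adjusted 0.373), the smallest these arrays can give, and 0.0238 (adjusted 0.560). Over all genes 0 members passed, and 14 acinar markers and 1 immediate early gene passed when adjusted over the list alone. The medians with slide as a block were +2.59 and +0.52. Within slides the acinar score was higher by 0.93 to 4.93 and the immediate early score by 0.12 to 1.05, each on 4 of 4 slides. Under normexp background correction the acinar median was +1.197.

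Hepatocyte markers and inflammation genes also stood higher in the pools fed 1.8 ug/g, and cell cycle genes lower. Of 30 hepatocyte markers, 26 were higher, with a median of +0.65, among them the liver fatty acid-binding gene fabp10a (+1.91 ± 0.94), the apolipoprotein genes apoa1b (+1.58 ± 0.96) and apoa4b.1 (+1.15 ± 0.66) and the bile acid synthesis gene cyp8b1.1 (+1.73 ± 1.02). Of 44 inflammation genes, 31 were higher, with a median of +0.15, among them socs3a (+1.77 ± 0.75), the chemokine receptor gene cxcr4b (+0.96 ± 0.37), the cyclooxygenase gene ptgs2b (+0.71 ± 0.27) and il6 (+0.56 ± 0.28). Of 39 cell cycle genes, 36 were lower, with a median of -0.27, among them ccne1 (-0.84 ± 0.59), the replication genes gins2 (-0.67 ± 0.49) and tyms (-0.68 ± 0.55) and the mitotic regulator gene foxm1 (-0.66 ± 0.56). Camera's adjusted p was 0.000435, 0.0239 and 0.0187, and the adjusted p was 0.974 for all 3 with an estimated correlation. No member passed over all genes or adjusted over the list alone. Slide as a block gave medians of +0.64, +0.20 and -0.25. Within slides the scores went the same way on 3 of the 4 slides for each list. Control replicate 3 was highest of the controls in oocyte markers, and without it the cell cycle and inflammation calls ended, with medians of -0.05 and +0.02. The cell cycle call also ended without control replicates 14 and 1 and 1.8 ug/g replicates 5 and 13 (medians -0.20, -0.27, -0.13 and -0.17), and its median was -0.47, -0.51 and -0.51 without control replicates 4 and 11 and 1.8 ug/g replicate 8. The inflammation call also ended without control replicates 4 and 11 and 1.8 ug/g replicate 5 (medians +0.18, +0.06 and +0.10), and its median was +0.28, +0.32, +0.23 and +0.23 without control replicates 14 and 1 and 1.8 ug/g replicates 13 and 8. Under normexp background correction the hepatocyte median was +0.13 and the inflammation median +0.05, and with the acinar, oocyte and hepatocyte scores as covariates the inflammation and cell cycle calls ended (+0.08 and -0.21).

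The comparison of the 1.8 ug/g diet with the 0.15 ug/g diet asks whether the doses differed from each other (4 and 6 pools). Among the higher genes with a symbol, 4 of the 5 of smallest p were immediate early genes: ier2a stood at +1.67 ± 0.32 (level 1.98 ± 0.17 SD at 0.15 ug/g and 3.65 ± 0.58 SD at 1.8 ug/g), fosab at +2.57 ± 0.51, btg2 at +2.12 ± 0.50 and junbb at +1.304 ± 0.33. The amino acid transporter gene slc43a1b stood at +0.72 ± 0.18. The lower genes of smallest p were pdgfrl, a receptor-like protein, at -1.29 ± 0.32, the folate enzyme gene dhfr at -1.13 ± 0.29, the follistatin gene fstb at -1.26 ± 0.33, the crystallin gene cryba1l2 at -0.97 ± 0.26 (2 of 3 probes in that direction) and the vimentin-like gene viml at -1.07 ± 0.31. Of the 4 arrays of the 1.8 ug/g diet, fstb was well above background on 2, and cryba1l2 and viml on 3 each. In limma, 0 of 21326 genes passed an adjusted p under 0.05, and the smallest adjusted p was 0.9998. At an unadjusted p under 0.05 there were 856 genes, 552 higher and 304 lower, where chance alone gives 1066.

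Of 33 immediate early genes, 30 were higher at 1.8 than at 0.15 ug/g, with a median of +0.78. The mean score was -0.05 ± 0.37 SD in controls (n = 5), -0.20 ± 0.16 SD at 0.15 ug/g (n = 6) and 0.49 ± 0.15 SD at 1.8 ug/g (n = 4), and control values of -0.63 to 0.36 overlapped those of both diets. All 21 acinar markers were higher at 1.8 than at 0.15 ug/g, with a median of +1.68, among them ela3l at +2.47 ± 0.91 and the chymotrypsin gene ctrb.3 at +1.91 ± 0.69. Of 28 erythrocyte markers, 23 were lower at 1.8 than at 0.15 ug/g, with a median of -0.70, among them gata1a at -1.13 ± 0.43, klf1 at -1.03 ± 0.49, tfr1a at -0.64 ± 0.26 and the biliverdin reductase gene blvrb at -0.97 ± 0.41. The adjusted p of camera was 1.1e-14, 1.0e-12 and 8.2e-08 for the 3 lists. The adjusted p was 0.126, 0.676 and 0.728 with an estimated correlation. None of the 3 calls held. The exact two-sided permutation p of the immediate early score was 0.00476 (adjusted 0.224), the smallest these arrays can give. Over all genes 0 members passed, and 12 immediate early genes, 0 acinar markers and 0 erythrocyte markers passed when adjusted over the list alone. Blocked by slide, the medians were +0.71, +1.57 and -0.74. Within slides the immediate early score was higher by 0.50 to 0.90 on 4 of 4, the acinar score was higher on 3 of 4 and the erythrocyte score was lower on 4 of 4. Under normexp background correction the acinar median was +0.82. Without 1.8 ug/g replicate 8 the acinar median was +1.09, and without 1.8 ug/g replicate 2 the erythrocyte median was -0.31.

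Heat shock, unfolded protein response and ribosomal protein genes stood higher at 1.8 than at 0.15 ug/g. Heat shock genes had 25 of 29 members higher and a median of +0.26, with hsp70l at +1.504 ± 0.54, hsp70.3 at +1.26 ± 0.53, ahsa1a at +1.76 ± 0.79 and dnajb1a at +0.46 ± 0.19. Unfolded protein response genes had 27 of 33 higher and a median of +0.14, with chac1 at +0.84 ± 0.33, ppp1r15a at +0.73 ± 0.29, trib3 at +0.39 ± 0.18 and the transcription factor gene atf4a at +0.31 ± 0.14. Cytosolic ribosomal protein genes had 69 of 77 higher and a median of +0.07, which was -0.00 with quantile normalization and +0.02 in the deposited value table, with rps29 at +0.26 ± 0.13, rps2 at +0.22 ± 0.13 and rps3a at +0.16 ± 0.13. In camera the adjusted p was 0.000569, 0.00487 and 0.0133. With an estimated correlation the adjusted p was 0.728, 0.728 and 0.837, and 0 members passed over all genes or adjusted over the list alone. With slide as a block the medians were +0.18, +0.14 and +0.05, the last no longer a call, and the scores were higher on 3, 3 and 4 of the 4 slides. The heat shock median was +0.12, +0.40 and +0.43 without 0.15 ug/g replicates 10, 6 and 7 and +0.17 and +0.54 without 1.8 ug/g replicates 5 and 13. The unfolded protein call ended without 1.8 ug/g replicate 2 (+0.10) or 0.15 ug/g replicate 16 (+0.07), and the ribosomal call without 0.15 ug/g replicates 10 and 16 (+0.02 and +0.06) or 1.8 ug/g replicates 13 and 8 (+0.08 and +0.06). With the acinar, oocyte and hepatocyte scores as covariates the medians were +0.46, +0.37 and +0.12, the heat shock median was +0.17 with no filter on dim probes, and the unfolded protein call ended with array weights (+0.11).

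Cell cycle, fibroblast, extracellular matrix and oxidative stress genes stood lower at 1.8 than at 0.15 ug/g. Cell cycle genes had 37 of 39 members lower and a median of -0.42, with the replication helicase gene mcm7 at -0.51 ± 0.23 (3 of 4 probes in that direction), the kinetochore gene nuf2 at -0.49 ± 0.25 and foxm1 at -1.05 ± 0.54. Fibroblast and epicardial markers had 16 of 18 lower and a median of -0.26, and extracellular matrix genes 31 of 44 lower and a median of -0.16, among them the proteoglycan gene lum, on both lists, at -1.23 ± 0.59, periostin postnb at -0.78 ± 0.38, clu at -0.93 ± 0.37, the collagen gene col5a3a at -0.77 ± 0.30 and the protease gene mmp14b at -0.55 ± 0.22. Oxidative stress genes had 26 of 35 lower and a median of -0.09, with gpx1a at -0.70 ± 0.29 and the peroxiredoxin gene prdx5 at -0.40 ± 0.18. Camera's adjusted p was 9.7e-07, 0.000318, 0.000544 and 0.0206. With an estimated correlation the adjusted p was 0.728, 0.728, 0.728 and 0.676, and 0 members passed over all genes or adjusted over the list alone. The medians with slide as a block were -0.33, -0.30, -0.15 and -0.09, and each score was lower on 3 of the 4 slides. The cell cycle median was -0.19, -0.18 and -0.25 without 0.15 ug/g replicate 7 and 1.8 ug/g replicates 5 and 13. Without 1.8 ug/g replicate 13 the fibroblast, matrix and oxidative stress calls ended (-0.17, -0.04 and -0.07). Without 1.8 ug/g replicate 8 the fibroblast median was -0.44, and without 0.15 ug/g replicate 7 the matrix median was -0.06. The oxidative stress call also ended without 0.15 ug/g replicates 7 and 16 and 1.8 ug/g replicate 2 (-0.09, -0.04 and -0.08). Under normexp background correction the matrix call ended (-0.17, adjusted p 0.111), as did the oxidative stress call (-0.05, 0.736), and with the acinar, oocyte and hepatocyte scores as covariates the matrix call ended (-0.06, 0.280) and the oxidative stress median was -0.16.

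**Figure D1:**
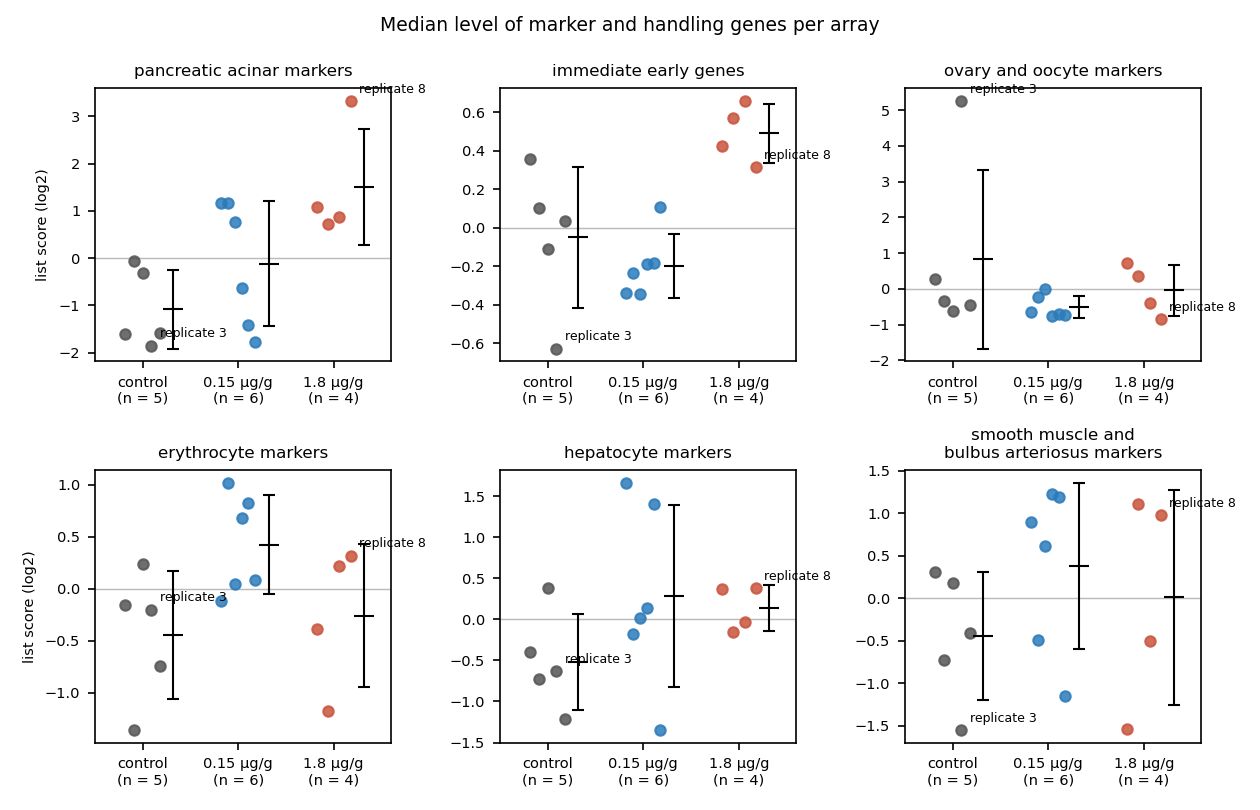
The plot gives, for each array (points), the list score, which is the median log2 signal of the list's genes after each gene was centred on its mean over the 15 arrays, by diet group, with the group mean and SD beside the points. The acinar scores of the 1.8 ug/g diet, 0.73 to 3.33, lie above the control scores, -1.86 to -0.07, and control replicate 3 stands apart in the oocyte score, at 5.26.

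The title of the series names mTOR signalling and the acidification of lysosomes, and the gene lists on these showed small differences. Of 41 mTOR signalling genes, 22 were higher at 0.15 ug/g and 23 at 1.8 ug/g than in controls, with medians of +0.01 and +0.04, and the median between the doses was -0.01. The first was -0.00 under normexp background correction. The kinase gene mtor stood at -0.10 ± 0.15 and -0.15 ± 0.16 against control, the amino acid sensor gene slc38a9 at +0.46 ± 0.21 and +0.34 ± 0.23. The GTPase gene rragcb and the kinase gene akt3a stood at +0.41 ± 0.21 and +0.34 ± 0.20 at 0.15 ug/g. The pathway inhibitor gene sesn1 stood at +0.39 ± 0.17 and lamtor2 at +0.29 ± 0.20 at 1.8 ug/g. Between the doses lamtor4 stood at -0.42 ± 0.18 and the mTOR inhibitor gene deptor at -0.41 ± 0.22. The S6 kinase gene rps6kb1b stood at -0.01 ± 0.14 and -0.05 ± 0.15, with 1 of its 3 probes in that direction and the first turning to +0.01 with quantile normalization. Of 20 subunits of the vacuolar ATPase, the proton pump of lysosomes, 12 were lower at 0.15 ug/g and 14 at 1.8 ug/g, with medians of -0.07 and -0.05, and 15 were lower at 1.8 than at 0.15 ug/g, with a median of -0.08. The subunit genes atp6v0a1a and atp6v1b2 stood at +0.37 ± 0.20 and -0.30 ± 0.21 at 0.15 ug/g (the latter in 2 of 3 probes), atp6v1e1b and atp6v1c1b at -0.39 ± 0.20 and -0.33 ± 0.19 at 1.8 ug/g, and tcirg1b and atp6v0e1 at -0.39 ± 0.27 and +0.39 ± 0.26 between the doses. The adjusted p of camera was 0.140, 0.772 and 0.372 for the mTOR list and 0.809, 0.272 and 0.135 for the ATPase list, and 0 members passed, over all genes or adjusted over the list alone. Slide as a block gave medians of +0.02, +0.03 and -0.01 for mTOR signalling and -0.05, -0.05 and -0.07 for the ATPase. Within slides the mTOR score was higher on 4 of the 4 slides at 0.15 ug/g (by 0.01 to 0.10, exact permutation p over all arrays 0.580), higher on 2 at 1.8 ug/g and lower on 3 between the doses, and the ATPase score was higher on 2, lower on 3 and lower on 3. No tested probe carried the names rptor or tfeb, and the arrays measure neither phosphorylation nor pH.

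Lysosomal hydrolase and membrane protein genes had 35 of 51 members higher at 0.15 ug/g than in controls, with a median of +0.08, and 35 of 51 lower at 1.8 than at 0.15 ug/g, with a median of -0.07. The transcription factor gene tfe3a, a regulator of lysosomal genes, stood at +0.59 ± 0.20 at 0.15 ug/g against control and at -0.44 ± 0.21 between the doses. The thioesterase gene ppt1 and the sialidase gene neu1 stood at +0.59 ± 0.21 and +0.45 ± 0.18 at 0.15 ug/g, the galactosidase gene glb1 at -0.71 ± 0.30 at 1.8 ug/g against control, and lamp2, a lysosomal membrane protein, at -0.32 ± 0.17, -0.05 ± 0.19 and +0.27 ± 0.18 in the 3 comparisons. The other list members named by the rule at 1.8 ug/g against control were higher: ppt1 at +0.40 and hexa at +0.31. In camera the adjusted p was 0.0152 and 0.0206 for the list, and the adjusted p was 0.547 and 0.728 with an estimated correlation, so neither call held. At 1.8 ug/g against control the list's median was -0.02 (adjusted p 0.918), and in all 3 comparisons 0 members passed over all genes or adjusted over the list alone. Blocked by slide, the medians were +0.11, -0.01 and -0.09 in the order 0.15 and 1.8 ug/g against control and 1.8 against 0.15 ug/g, and the score was higher on 3, higher on 2 and lower on 4 of the 4 slides. The call at 0.15 ug/g ended without control replicates 14 and 11 and 0.15 ug/g replicate 10 (medians +0.05, +0.03 and +0.06). The call between the doses ended without 0.15 ug/g replicate 10 and 1.8 ug/g replicate 13 (-0.08 and -0.02), and its median was -0.12 without 0.15 ug/g replicate 7 and -0.12 without 1.8 ug/g replicate 8. The first call also ended under normexp background correction (+0.04, adjusted p 0.586), with probes well above background on every array (+0.07, 0.0598), with array weights (+0.07, 0.117) and with the acinar, oocyte and hepatocyte scores as covariates (+0.04, 0.0870). The second ended under normexp (-0.07, adjusted p 0.789) and with array weights (-0.04, 0.0542), and it was held at a larger median with those covariates (-0.15), with quantile normalization (-0.11) and in the deposited value table (-0.11). Of 32 autophagy genes, 21 were higher at 0.15 ug/g and 18 at 1.8 ug/g than in controls, with medians of +0.05 and +0.04, and the median between the doses was -0.04 (camera's adjusted p 0.211, 0.828 and 0.372). The autophagosome gene map1lc3b stood at -0.36 ± 0.16 and -0.35 ± 0.18 against control, wdr45 at +0.53 ± 0.20 at 0.15 ug/g, and map1lc3a at -0.33 ± 0.13 and -0.26 ± 0.14, with 1 of its 3 probes in that direction.

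**Figure D2:**
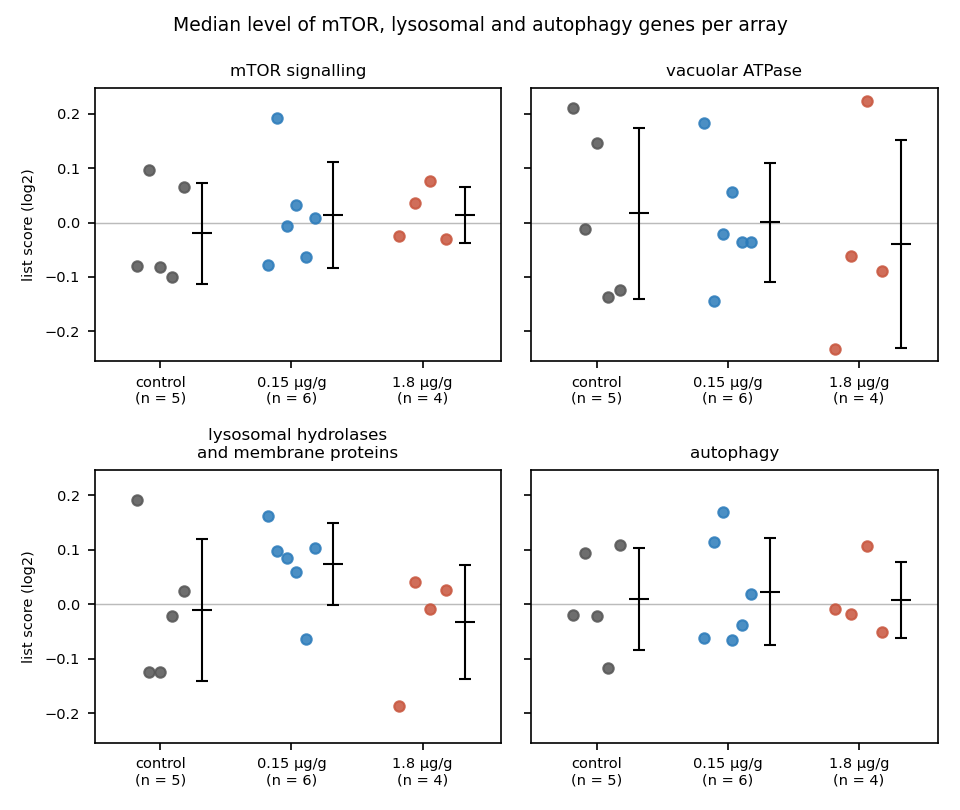
The plot gives the list score of each array (points, log2) for 4 lists by diet group, with the group mean and SD beside the points. The mTOR signalling scores lie between -0.10 and 0.19 on all arrays, and the 3 groups overlap in each list.

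**Figure D3:**
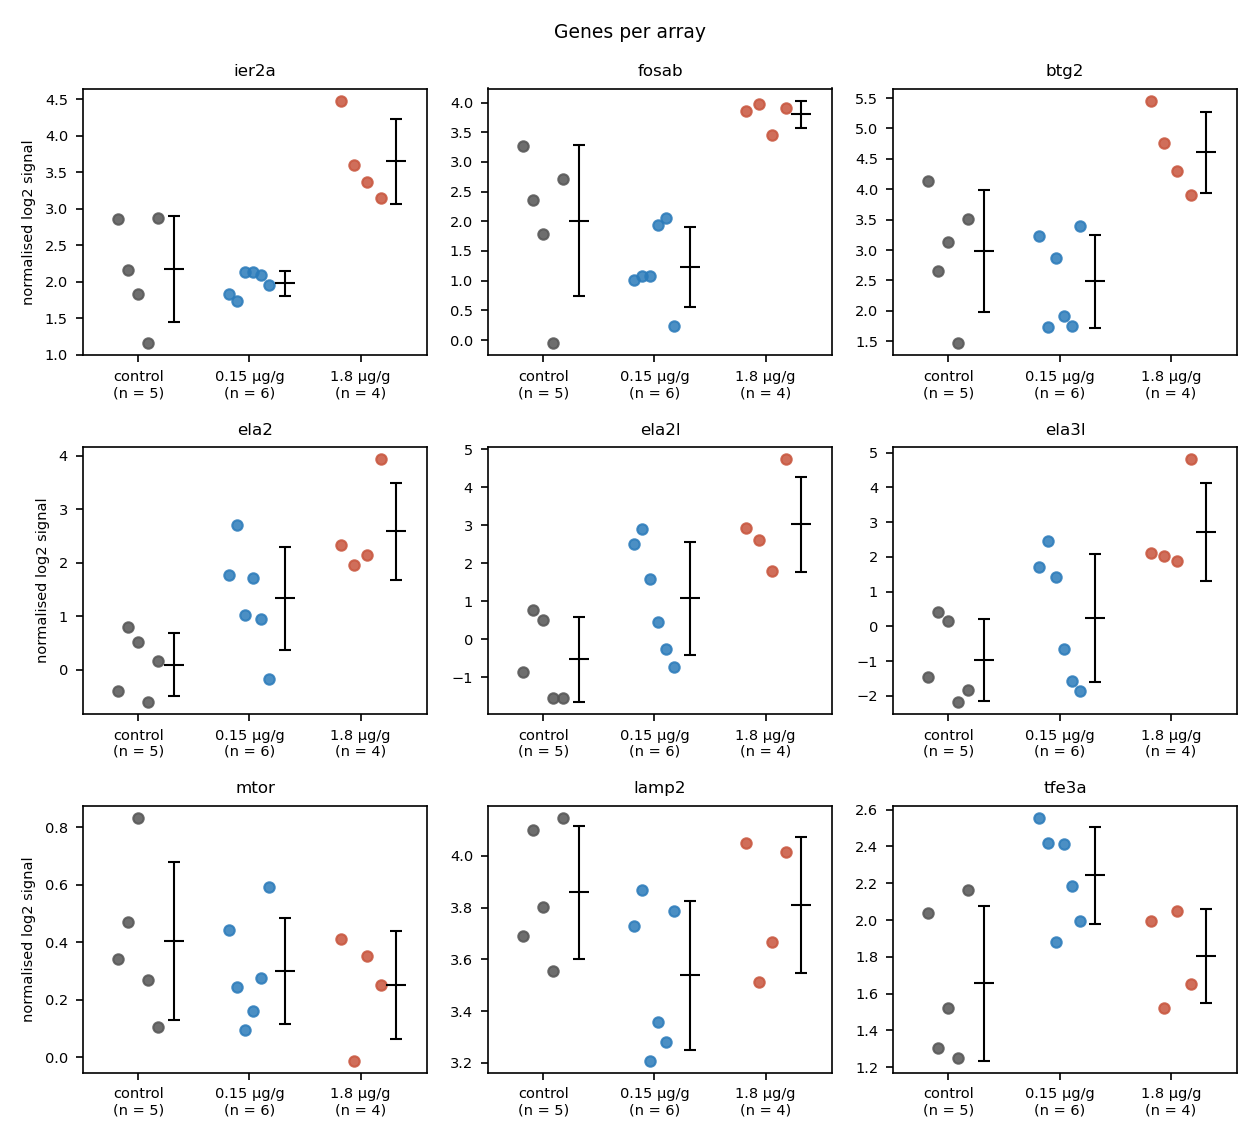
The plot gives the normalised log2 signal of 9 genes on each array (points) by diet group, with the group mean and SD beside the points. For ier2a the 4 arrays of the 1.8 ug/g diet average 3.65 and the 5 controls 2.18, and mtor averages 0.40 in controls, 0.30 at 0.15 ug/g and 0.25 at 1.8 ug/g.

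The other lists did not pass in any comparison. Energy and lipid metabolism lists (oxidative phosphorylation, fatty acid oxidation, glycolysis, the tricarboxylic acid cycle, cholesterol synthesis, and fatty acid and triglyceride synthesis) had medians of -0.03 to +0.03 at 0.15 ug/g, -0.10 to +0.04 at 1.8 ug/g and -0.07 to +0.09 between the doses. Heart muscle lists (sarcomere, stress and fetal programme, calcium and ion channels, cardiomyocyte markers, and atrophy ligases and calpains) had medians of -0.15 to -0.09, -0.04 to +0.00 and +0.08 to +0.15 in the same order. The natriuretic peptide gene nppa, a marker of cardiac strain, stood at -0.23 ± 0.19 and +0.01 ± 0.21 against control, the latter -0.07 with quantile normalization and in the deposited value table. Hormone, xenobiotic and clock lists (insulin and IGF signalling, oestrogen and sex steroids, glucocorticoid and hypoxia targets, thyroid hormone, xenobiotic metabolism and circadian clock) had medians of -0.15 to +0.04, -0.08 to +0.16 and -0.00 to +0.29. The dioxin-responsive gene cyp1a stood at +0.23 ± 0.48 and -0.31 ± 0.53 against control. Interferon response, complement and coagulation, thrombocyte, and apoptosis lists had medians of -0.02 to +0.22, -0.18 to +0.24 and -0.17 to +0.04. Endothelial, skeletal muscle, gill and neural markers had medians of -0.14 to +0.02, -0.02 to +0.19 and +0.10 to +0.17. Translation factor and proteasome genes had medians of -0.00 to +0.04, -0.00 to +0.06 and -0.05 to +0.08. The smallest camera adjusted p among these lists was 0.0600 at 0.15 ug/g (interferon response), 0.0579 at 1.8 ug/g (apoptosis and p53 targets) and 0.0817 between the doses (cardiac sarcomere).

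Of the 47 lists, 11 passed camera with its preset correlation at 0.15 ug/g against control (8 higher and 3 lower), 6 at 1.8 ug/g (4 higher and 2 lower) and 11 between the doses (5 higher and 6 lower). With an estimated correlation 0 lists passed in each comparison, and the smallest adjusted p was 0.321, 0.155 and 0.126. With fry, which asks whether a list's genes move on balance one way, 0 lists passed, with smallest adjusted p of 0.141, 0.216 and 0.0614. In the exact permutation of list scores, 2, 2 and 4 of the 47 lists had an unadjusted p under 0.05, where chance gives 2.35, and among the lists that passed camera these were 2 of 11, 2 of 6 and 1 of 11. At the preset correlation of camera, the first count (11) was 18 without control replicate 14 and 17 without 0.15 ug/g replicate 15. The second (6) was 14, 12 and 13 without control replicates 14 and 1 and 1.8 ug/g replicate 2. The third (11) was 6 without 1.8 ug/g replicate 13. The median and the mean of each list that passed had the sign of its test.

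Across the 3 diets together, limma's F test found 0 of 21326 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.9998 and 918 genes at an unadjusted p under 0.05. The responses of the 2 doses against control correlated across genes at r = 0.530 (covariance 0.0757), and 67.2% of genes had the same sign. Both share the 5 control arrays, and 200 simulations of unchanged groups against shared controls gave a mean r of 0.494 (highest 0.524) and a mean covariance of 0.0714 (highest 0.0782). Leaving out 1 array at a time gave r a jackknife standard error of 0.186. An r above the highest simulated one therefore does not establish agreement of the doses beyond the shared controls. With the controls split into 2 and 3 arrays, over 20 such splits, r averaged -0.04 (-0.15 to 0.12) and the covariance averaged -0.0104. At an unadjusted p under 0.05, 72 genes were higher at both doses and 137 lower at both, where independent lists give 7.67 and 14.4 and 20 simulations of unchanged groups gave a mean of 118 (highest 143) and 119 (highest 136). No error was estimated for these overlaps, 72 being below the simulated mean and 137 just above the highest simulated count. They do not establish agreement of the doses beyond the shared controls either. The genes in these overlaps did not pass the adjusted test at either dose.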

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

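The tests of slide, chance between pools, the acinar covariate, handling and the ovary sample were chosen only after the result was seen, and the tests of admixed pancreas and ovary and of other splits of the arrays were chosen before. Within each group the highest or lowest array was set against the gap to its nearest neighbour by Dixon's criterion, which marks about 1 in 20 groups by chance. It marked 6 of 60 groups of list scores and 23 of 393 groups of gene values.

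Among list scores, control replicate 3 stood at 5.26 for oocyte markers (other controls -0.62 to 0.27), and 1.8 ug/g replicate 8 at 3.33 for acinar markers (others 0.73 to 1.07). In the 0.15 ug/g group, replicate 10 stood at 1.05 for leukocyte markers (others -0.25 to -0.01) and at -0.30 for ribosomal proteins (others -0.07 to 0.04), replicate 16 at 0.19 for oxidative stress genes (others -0.01 to 0.06) and replicate 9 at 0.11 for immediate early genes (others -0.34 to -0.19). Among genes, control replicate 3 stood apart at 2.59 for zar1l, 2.06 for zp3a.2 and 0.987 for junbb, control replicate 14 at 2.69 for ppt1, 4.49 for bnip3lb and 2.22 for mmp14b, control replicate 4 at 1.02 for atp6v1f and control replicate 1 at 3.35 for atp6ap1b. At 0.15 ug/g, replicate 10 stood apart at -2.61 for slc6a1a, -3.45 for zp3a.2 and 9.27 for rps14, replicate 16 at 0.22 for lyz, -3.84 for ppp2r2bb and -3.15 for rassf4a, replicate 9 at 5.08 for rbp4 and 3.96 for trib3, replicate 15 at 0.67 for ppp1r15a and 1.88 for clu, and replicate 7 at -6.69 for zar1l, which was not well above background on any array of that group, so this value is noise of the background. At 1.8 ug/g, replicate 8 stood apart at 4.81 for ela3l and 2.96 for laptm5, and replicate 13 at -2.78 for gad1b and -3.13 for zp3a.2. Gene values are log2 signals relative to the array's 75th percentile.

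Digestive enzyme transcripts were higher on the 1.8 ug/g arrays. A difference between slides is argued against by the layout, since each slide held every group. With groups spread so, slide as a block could move the list's median shift little, and it was +2.59. Admixed exocrine pancreas, which lies along the gut and outside the heart, is a candidate explanation. Of 24 acinar genes fixed outside the list, 7 were tested. Their median was +1.01, with 6 of the 7 higher, only just past the bound of 1 set for it. The elastase genes cela1.3 (+1.01 ± 0.40), cela1.4 (+0.40 ± 0.33) and cela1.6 (+3.29 ± 0.92) are related to members of the list. The genes c6ast3 (+2.40 ± 0.82) and c6ast4 (+1.81 ± 0.75) encode proteases too. These are therefore not independent of the list. The remaining genes, bhlha15 (+0.33 ± 0.38) and gatm (-0.03 ± 0.57), moved by less than their standard errors. By comparison, 5 endocrine pancreas genes had a median of -0.01 and 11 intestine genes +0.41. Only 1 split of the 9 arrays, the real one, gave a score difference as large (exact permutation p = 0.00794), the smallest p these arrays can give, so the adjusted 0.373 decides nothing for a lone list among 47. Chance between pools was not excluded, since the list was picked from the 47 by its score. An effect of the diet on pancreas or feeding is the biological explanation the design gives, and it was not tested.

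Immediate early genes were higher on the 1.8 ug/g than on the 0.15 ug/g arrays. A difference between slides is again argued against by the layout, and the shift was +0.71 with slide as a block. Admixed pancreas is argued against by a score difference of 0.80 ± 0.19 with the acinar score as a covariate against 0.69 ± 0.16 without. Handling or time before freezing that differed between diets could also raise them: across the 15 arrays, less group means, their score correlated with that of the heat shock genes at r = 0.256 (permutation p = 0.367; Spearman 0.275, permutation p = 0.319). Heat shock genes were higher too in this comparison (25 of 29, median +0.26, camera's adjusted p 0.000569, higher on 3 of 4 slides). That call did not hold with an estimated correlation (adjusted p 0.728). They were not higher at 1.8 ug/g against control (16 of 29 lower, median -0.06, camera's adjusted p 0.622, lower on 3 of 4 slides), so handling is neither excluded nor shown. Only 1 split of the 10 arrays, the real one, gave a difference as large (exact permutation p = 0.00476), the smallest p these arrays can give, so the adjusted 0.224 decides nothing for a lone list. Chance was not excluded, since this list too was picked by its score, and a response of the heart to the dose was not tested apart from these.

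Oocyte transcripts on control replicate 3 set the difference of the oocyte list at both doses. An ovary sample in place of heart is argued against by its cardiomyocyte score, -0.093 from the mean of the other controls. Ovary or egg RNA admixed to 1 pool is a candidate explanation: 13 oocyte and maternal genes outside the list had a median of +2.32 on this array against the other controls, with 8 of the 13 higher. The design gives no biological explanation for 1 array, and none was tested.

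Other splits of the arrays, 100 per comparison with the real one, gave as many genes at an unadjusted p under 0.05 and as many lists, so chance could not be excluded for those counts. For genes at an unadjusted p under 0.05, 51 of 100 splits gave as many as the 1134 at 0.15 ug/g against control (highest other 3644), 68 as many as the 818 at 1.8 ug/g (highest other 2561), 34 as many as the 856 between the doses (highest other 1706) and 48 as many as the 918 across the 3 diets (highest other 2300). For genes at limma's adjusted p under 0.05 the real count was 0, which all 100 splits must reach in each of the 4 tests, so this count says nothing about chance. The highest others were 2, 5, 27 and 2. For gene lists, 76 splits gave at least the real 11 at 0.15 ug/g (highest other 22), 97 at least the real 6 at 1.8 ug/g (highest other 23) and 56 at least the real 11 between the doses (highest other 21). Some splits called several times more than the real one, for genes at both doses against control and for lists at 1.8 ug/g. The median of the other splits there was 1158 and 985 genes, and 13 lists. Whether a structure of the samples other than diet gave the highest counts was not tested.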

How the results depend on the processing

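Normexp on the median signal (the mean signal is absent), the exact permutation of list scores, the fit without control replicate 3 and 1.8 ug/g replicate 8 together and the acinar, oocyte and hepatocyte covariates were chosen after seeing the data. Scan date was not a block, as all arrays share 1 scan day. Pairing by replicate number was impossible, as no number occurs in more than 1 group. Arrays were matched by slide alone, as a block and within slides. Between 63.8% and 75.7% of spots were well above background, which limits dim genes. Normexp's offset of 50 shrinks their changes. Other causes of moves were not tested. Of 1209 list values under alternatives, 1022 kept direction and side of the threshold, 156 were weaker, 7 stronger and 24 reversed. Of 5017 values of named genes, 39 reversed direction.

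In the order 0.15 and 1.8 ug/g against control and 1.8 against 0.15 ug/g, the lists past the threshold were 11, 6 and 11. They were 17, 18 and 22 under normexp, 0, 0 and 0 with an estimated correlation in camera, 0, 0 and 0 with fry and 0, 0 and 0 in the exact permutation, and 11 at 1.8 ug/g with the mean of all probes of a gene. At this number of arrays a lone list could not pass the exact permutation adjusted over the lists (smallest possible 0.102, 0.373 and 0.224), while 3, 8 and 5 lists at the smallest p would pass. Unadjusted, 2, 2 and 4 lists had a permutation p under 0.05, where chance gives 2.35. In camera with its preset correlation, leaving out 1 array gave 9 to 18, 5 to 14 and 6 to 14 lists. The first count was 18 and 17 without control replicate 14 and 0.15 ug/g replicate 15. The second was 14, 12 and 13 without control replicates 14 and 1 and 1.8 ug/g replicate 2. The third was 6 without 1.8 ug/g replicate 13. Genes past limma's adjusted p were 0 in each comparison and 1134, 818 and 856 at an unadjusted p under 0.05, with 918 in the F test. With only the 2 groups compared, 1 gene passed at 1.8 ug/g against control, a probe without a gene symbol (adjusted p 0.0238), chosen after its values were seen. It was not well above background on any control array and was at least 1.22-fold higher in the treated pools, and with all groups its adjusted p was 0.9996.

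Beside those given with the results, calls of lists ended (median, adjusted p) under these settings. Under normexp at 0.15 ug/g: leukocyte +0.15, 0.0920, and oxidative stress +0.08, 0.351. With the covariates at 0.15 ug/g: leukocyte +0.11, 0.392, and oxidative stress +0.07, 0.209. With the covariates at 1.8 ug/g: cell cycle -0.21, 0.705, and inflammation +0.08, 0.705. With array weights at 0.15 ug/g: inflammation +0.10, 0.205, and leukocyte +0.05, 0.390. With array weights at 1.8 ug/g: inflammation +0.13, 0.163, and between the doses unfolded protein response +0.11, 0.0542. With probes well above background on every array: leukocyte +0.21, 0.0598, and oocyte -0.41, 0.155, at 0.15 ug/g, and oocyte -0.73, 0.150, at 1.8 ug/g. With no filter on dim probes: inflammation +0.14, 0.0616, at 1.8 ug/g, and ribosomal +0.07, 0.113, between the doses. Between the doses, ribosomal +0.05, 0.0515, with median centring, +0.05, 0.135, with slide as a fixed block and +0.02, 0.443, in the authors' value table. With only the 2 groups compared: oocyte -0.69, 0.0709, at 1.8 ug/g. Without control replicate 3 and 1.8 ug/g replicate 8 together: inflammation +0.02, 0.224, and oocyte -0.16, 0.677, at 0.15 ug/g, inflammation +0.08, 0.190, at 1.8 ug/g, and ribosomal +0.06, 0.268, between the doses.

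Other medians of lists moved by over 1.5 times with the call kept, beside those given with the results. Ribosomal proteins between the doses were +0.17 under normexp. Oxidative stress at 0.15 ug/g was +0.09 with quantile normalization, +0.09 in the authors' value table and +0.07 with the mean of all probes of a gene. Heat shock between the doses was +0.17 with probes well above background on every array and with array weights, and inflammation at 0.15 ug/g +0.10 with no filter. Without control replicate 3 and 1.8 ug/g replicate 8 together: heat shock -0.50, smooth muscle +0.47 and oxidative stress +0.08 at 0.15 ug/g, hepatocyte +0.42 at 1.8 ug/g, and fibroblast -0.44, acinar +1.09 and lysosomal -0.12 between the doses.

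Reversed under quantile normalization: ribosomal proteins between the doses -0.0014, nppa at 1.8 ug/g -0.0718 and rps6kb1b at 0.15 ug/g +0.0108. Under median centring: nppa at 1.8 ug/g -7.0e-05. In the authors' value table: nppa at 1.8 ug/g -0.0714 and rps6kb1b at 0.15 ug/g +0.0119. With slide as a fixed block: rps6kb1b at 0.15 ug/g +0.0274. Under normexp: mTOR signalling at 0.15 ug/g -0.0026, and between the doses bnip3la -0.0548 and rps6kb1b +0.00918. With array weights: mTOR signalling between the doses +0.0104 and lamp2 at 1.8 ug/g +0.00801. With the mean of all probes of a gene: at 0.15 ug/g the vacuolar ATPase +0.0112, map1lc3a +0.00871 and rps6kb1b +0.0984, and at 1.8 ug/g lysosomal genes +0.0544, lamp2 +0.0515, map1lc3a +0.0405, nppa -0.0500 and rps6kb1b +0.0736. With the acinar, oocyte and hepatocyte scores as covariates: at 0.15 ug/g inflammation -0.00773 and myh11a -0.0151, and at 1.8 ug/g mTOR signalling -0.0498, slc38a9 -0.0527 and lhx8a +0.153, whose sign carries nothing since it was not well above background on any 1.8 ug/g array. Without control replicate 3 and 1.8 ug/g replicate 8 together: mTOR signalling at 0.15 ug/g -0.0219, and at 1.8 ug/g autophagy -0.00728, nppa -0.0323 and oocyte markers +0.499, which passed in that direction (adjusted p 0.0107). This setting gave lamp2 -0.192 and rps6kb1b -0.155 at 1.8 ug/g and 15 lists between the doses.

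Leaving out 1 array at a time gave, at 0.15 ug/g, -0.108 to +0.497 for leukocyte markers, -0.0243 to +0.0343 for mTOR signalling, -0.108 to +0.0257 for the vacuolar ATPase, -0.00553 to +0.525 for cyp1a, -0.178 to +0.00402 for mtor and -0.113 to +0.0584 for rps6kb1b. At 1.8 ug/g it gave -0.0131 to +0.0547 for autophagy, -0.0650 to +0.0687 for lysosomal genes, -0.0219 to +0.0762 for mTOR signalling, -1.04 to +0.207 for oocyte markers, -0.127 to +0.0516 for lamp2, -0.0737 to +0.114 for nppa and -0.154 to +0.0218 for rps6kb1b. Between the doses it gave -0.0528 to +0.0348 for mTOR signalling, -0.104 to +0.0370 for mtor and -0.119 to +0.0313 for rps6kb1b.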

Other observations

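Control replicate 3 also stood apart in the genes as a whole: its value on the first principal component, which held 13.97% of the variance, was 103.5. Its cell cycle score was 0.77 against a mean of -0.21 on the other controls, though another array reached 1.18. Its immediate early score was -0.63 against 0.10. Smooth muscle markers stood at -1.56 against -0.16 and acinar markers at -1.86 against -0.90, each the lowest of all arrays. The next lowest arrays were close, at -1.545 and -1.773. Interferon response and inflammation genes were lower on it, at -0.74 and -0.61 against means of -0.00 and 0.00 on the other controls. These values belong to 1 pool, and no test was run on them.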
